A study of Homo sapiens with 12 samples.

How the data were processed

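RNA was measured in OCI-LY1 and VAL, which are human diffuse large B-cell lymphoma lines. Per the labels' protocols, cells were transduced with an empty vector, wild-type BCL7A or delta27-BCL7A, a splice-site mutant, in 3 cycles of infection at a multiplicity of 2. BCL7A was given as its short and long isoforms. Per the labels' protocols, reporter-positive cells were sorted on a fluorescent protein, and RNA was collected 10 days after transduction for OCI-LY1 and 17 days after it for VAL. Line and day therefore cannot be told apart. Each of the 6 groups (line by construct) holds 2 libraries from independent transductions, per the labels. Libraries of polyadenylated RNA were made with a stranded kit, per the labels.

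The deposited values are raw counts of reads per gene, 1 table per library, per the file headers and values: whole numbers against versioned Ensembl gene identifiers, with 5 closing lines that count the reads given to no gene. Per the submitters' processing notes, STAR 2.6.1b, HTSeq 0.11.2, R 3.6.1, edgeR and DESeq2 were used with the builds GRCh38 and hg38. The notes give neither the annotation release, the strand setting of the counting nor any filter. The tables held 60603 genes, of which 58483 matched GENCODE release 29 on GRCh38 by identifier without version and 60261 had a symbol in the reference table. Coordinates come from that annotation.

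Reads of near-identical gene copies cannot be divided with certainty, which concerns the HLA genes, SULT1A2 and the mitochondrial transcripts, and overlapping or antisense genes cannot be separated where the strand setting is unknown. The counts also cannot divide BCL7A reads into those of the vector and of the cell's own gene, nor into wild-type and mutant forms.

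Counts per gene were modelled with edgeR 4.0.16 in R 4.3.3: scaling by trimmed mean of M values (TMM), a filter on low counts with a minimum count of 10, and a robust quasi-likelihood fit over the 12 libraries with 6 group means. The fit kept 17057 genes, left 6 residual degrees of freedom (median 35.2 with the information shared between genes) and gave a common biological coefficient of variation of 3.7%. CPM values were computed here from the counts with TMM scaling. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a contrast and a threshold of 0.05. The 12 contrasts were the 3 pairs of constructs within each line, their means over the lines and the differences between the lines, taken as VAL minus OCI-LY1. Standard errors (SE) of log2 fold changes come from the fit.

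The 30 gene lists were written from textbook knowledge before the data were examined, as were the contrasts, the tests, the rule for named genes and most alternatives; 26 lists had at least 3 members tested. They were tested with limma camera on voom values (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. Of the 146 list calls over the 12 contrasts, 3 held with an estimated correlation: the NF-kB targets and MHC class II genes in VAL wild-type against delta27-BCL7A, and the p53 targets in wild-type BCL7A against empty vector over both lines.

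Named genes were BCL7A and, among protein-coding genes past the threshold with a mean of at least 1 CPM and separated libraries, the largest changes in each direction of each contrast, the largest among genes called in both lines, the largest line differences and up to 4 members per list with the smallest p. The texts give examples from these. A fold against a group with 0 counts was bounded with a floor of 3 counts over the group; with 1 to 3 counts, a ratio with its exact 95% counting interval is given. Intervals and bounds of that kind cover counting error only.

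Alternatives were another scaling (RLE), DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts, a fit of each line alone, a minimum log2 fold change of 1, the replicate number as a block, and leaving out each library in turn. Where this left 1 library in a group, its spread was taken from the other groups. A correction of each library for trends with GC content and transcript length, and a fit without mitochondrial genes, were added after the data were seen. Also added then were a fit with each construct against its own empty vector library, and a check for reads of the other line. The latter used autosomal transcripts with at least 5 CPM in each library of the other line and 0 counts with empty vector. GC content was known for 98.9% of the genes tested.

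The methods were tested on simulated counts drawn from the empty vector means of each line, with known changes added, of which the fit kept 16778 genes. Each gene had the same spread in all groups of a line, so uneven spread between groups was not simulated. In a simulated OCI-LY1 wild-type against empty vector comparison, 76 of 100 genes changed by 1.5-fold and 88 of 100 changed by 2-fold were recovered, with 5 unchanged genes called. In the simulated VAL comparison, 77 and 84 of 100 were recovered, with 22 unchanged genes called. With a GC trend added to the simulated counts, 16735 genes were kept. The uncorrected fit then called 582 unchanged genes for OCI-LY1 and 915 for VAL in the same comparison, and the corrected fit 6 and 25. All within-line comparisons showed a GC trend and are reported uncorrected, so their counts are to be read beside the corrected ones. Depth was 21839547 to 24935893 gene counts per library. Levels of sex-linked genes and of some genes that met the rule for named genes are not reported here.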

Results

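Messenger RNA was sequenced from 12 libraries of 2 diffuse large B-cell lymphoma lines, OCI-LY1 and VAL. Each line carried an empty vector, wild-type BCL7A or delta27-BCL7A, a splice-site mutant, with 2 libraries per group. BCL7A is a subunit of the SWI/SNF chromatin remodelling complex, and the series title gives its role as a tumour suppressor in this lymphoma as the subject. The comparisons ask which genes changed when BCL7A was raised, and whether the mutant form differed from the wild type. Total gene counts per library lay between 21839547 and 24935893. Replicates correlated across genes at 0.994 to 0.995 on the log scale within the 6 groups. The libraries of VAL with wild-type BCL7A differed most from each other, with a chi-square of 7.5 per degree of freedom against 1.51 to 3.2 in the other 5 groups. The share of reads with low alignment quality was 3.92% and 3.01% in the OCI-LY1 delta27-BCL7A libraries, against 4.8% and 6.9% with empty vector and 6.41% and 6.6% with wild-type BCL7A. In VAL it was 3.87% and 5.66% with delta27-BCL7A, 4.72% and 5.76% with empty vector and 6.0% and 6.37% with wild-type BCL7A.

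BCL7A (ENSG00000110987.8; GRCh38 chromosome 12, 122019422 to 122062044, plus strand) rose with both constructs in both lines. In OCI-LY1 it went from 156 CPM ± 1.6 (SD, n = 2) with empty vector to 577 ± 1.1 with wild-type and 581 ± 10 with delta27-BCL7A. In VAL it went from 287 CPM ± 5.5 (SD, n = 2) to 463 ± 13 and 488 ± 3.8. These were rises of 3.69-fold and 3.72-fold in OCI-LY1 (edgeR quasi-likelihood adjusted p = 2.26e-26 and 1.92e-26) and of 1.61-fold and 1.70-fold in VAL (adjusted p = 1.81e-12 and 7.47e-14, same test). Wild-type against delta27-BCL7A differed by a log2 fold change of -0.01 in OCI-LY1 (95% interval -0.10 to 0.08) and of -0.07 in VAL (95% interval -0.17 to 0.02). The edgeR quasi-likelihood test gave adjusted p = 0.964 and 0.346 for these, so no difference in BCL7A transcript level was detectable at this depth. The counts cannot separate vector reads from the cell's own, nor wild-type from mutant ones.

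**Figure D1:**
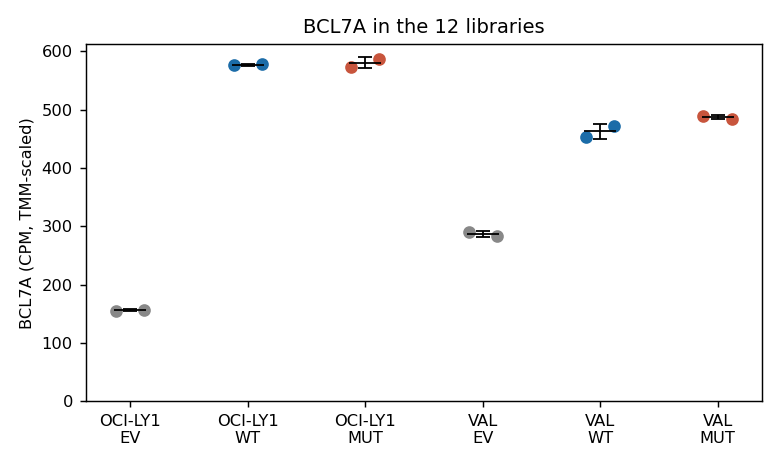
BCL7A in CPM (TMM-scaled, vertical axis) in the 12 libraries by line and construct; points are libraries, dashes the means and bars the SD (n = 2). BCL7A rose from a mean of 156 to 577 and 581 in OCI-LY1, and from 287 to 463 and 488 in VAL.

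In OCI-LY1, wild-type BCL7A raised 13 of 24 p53 target genes and lowered 11 of 27 genes of glycolysis and the hypoxia response relative to empty vector. Camera called both lists, but neither with an estimated correlation (adjusted p = 0.0524 for both). ZMAT3, an RNA-binding p53 target, rose from 150 CPM ± 1.0 (SD, n = 2) to 251 ± 11, MDM2, the ubiquitin ligase that restrains p53, from 356 ± 4.8 to 512 ± 2.3, and the cell-cycle inhibitor CDKN1A from 107 ± 0.34 to 142 ± 6.2. VEGFA (ENSG00000112715.21; chromosome 6, 43770184 to 43786487), the angiogenic growth factor, fell from 36.2 CPM ± 2.4 to 17.1 ± 1.2, and the glycolytic aldolase ALDOC fell from 67.0 ± 0.51 to 42.5 ± 5.6. Among the largest rises were SULF2, an extracellular sulfatase (log2 fold change 1.45, SE 0.30), the transcription factor BCL11A (1.18, SE 0.20), the kinase PLK2 (0.99, SE 0.13) and the death receptor FAS (0.95, SE 0.13). Among the largest falls were LRRC32, which presents latent TGF-beta (-1.73, SE 0.21), the receptor phosphatase PTPRF (-1.57, SE 0.14) and the small GTPase DIRAS1 (-1.52, SE 0.12).

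Of the 24 p53 targets tested, 13 were higher and 1 lower in that comparison (15 and 1 adjusted over the list alone; median log2 fold change 0.25; camera adjusted p = 9.45e-10, and adjusted p = 0.0524 with an estimated correlation). Of 27 glycolysis and hypoxia genes, 11 were lower and 1 higher (17 and 1 adjusted over the list alone; median -0.17; camera adjusted p = 1.64e-09, and adjusted p = 0.0524 with an estimated correlation). Among 22 B cell transcription factors, 11 were higher and 0 lower, with 12 and 0 adjusted over the list alone, RUNX1 (0.51, SE 0.07) and FOXO1 (0.35, SE 0.05) among them; camera gave an adjusted p = 7.44e-07, and adjusted p = 0.49 with an estimated correlation. Unfolded protein and integrated stress response genes were lower in 7 of 24 and higher in 0 (8 and 0 adjusted over the list alone), with DDIT4, an mTOR inhibitor, at -0.68 (SE 0.07); camera gave an adjusted p = 0.00101, and adjusted p = 0.49 with an estimated correlation. Histone transcripts without a poly(A) tail were higher in 3 of 15 and lower in 0 (5 and 0 adjusted over the list alone; median 0.31; camera adjusted p = 0.00947) and mitochondrial transcripts in 3 of 13 (5 adjusted over the list alone, where 1 was lower; median 0.10; camera adjusted p = 0.0136), both with an adjusted p = 0.586 with an estimated correlation. The libraries were made from polyadenylated RNA, so the histone counts cannot separate transcript level from how these transcripts passed that selection. In total 1951 of 17057 genes passed the edgeR quasi-likelihood test, 1063 higher and 888 lower. Of these, 126 changed by a log2 fold change of at least 1 in size, 26 higher and 100 lower. The named changes kept their call without each library in turn, whereas the count fell to 744 and 1178 without empty vector replicate 1 or 2, and to 800 and 883 without wild-type replicate 1 or 2. Fold changes also fell with the GC content of the transcripts, with a Spearman correlation of -0.342 across genes, which are not independent replicates.

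Delta27-BCL7A in OCI-LY1 also raised ZMAT3 and MDM2 over empty vector, to 244 CPM ± 2.7 (SD, n = 2) and 518 ± 9.6, and lowered VEGFA to 20.5 ± 1.3 and ALDOC to 36.0 ± 1.3. CDKN1A stayed at 104 ± 7.3 against 107 ± 0.34 (log2 fold change -0.04, SE 0.06; edgeR quasi-likelihood adjusted p = 0.693). TMED7, a cargo receptor of the secretory pathway, rose by a log2 fold change of 1.09 (SE 0.10), and CHAC1, an enzyme that degrades glutathione, fell by 1.59 (SE 0.34). UTP20 (0.38, SE 0.06) and RRS1 (0.33, SE 0.06), which act in ribosome biogenesis, rose. HLA-DMA, which helps load peptides on MHC class II, fell (-0.69, SE 0.08).

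Of 27 MYC and ribosome biogenesis genes, 12 were higher and 1 lower (13 and 1 adjusted over the list alone; camera adjusted p = 8.01e-05, and adjusted p = 0.585 with an estimated correlation). Glycolysis and hypoxia genes were lower in 11 of 27 and higher in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 7.31e-05, and adjusted p = 0.441 with an estimated correlation). The p53 targets were higher in 10 of 24 and lower in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0026, and adjusted p = 0.547 with an estimated correlation). The heat shock genes were higher in 5 of 16, CHORDC1 (0.43, SE 0.05) and HSPA1B (0.45, SE 0.11) among them, and lower in 1 (6 and 2 adjusted over the list alone); camera gave an adjusted p = 0.016, and adjusted p = 0.585 with an estimated correlation. In total 3338 genes passed the edgeR quasi-likelihood test, 1776 higher and 1562 lower. The count was 2002 and 2068 without empty vector replicate 1 or 2, and 1265 without delta27-BCL7A replicate 2. The Spearman correlation of fold change with GC content was -0.574 across genes, and of the 3338 genes 1802 remained called in the same direction after a correction for GC content and length.

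Wild-type against delta27-BCL7A in OCI-LY1 showed higher LGALS9, the glycan-binding protein galectin-9, at 7.98 CPM ± 0.45 (SD, n = 2) against 3.68 ± 0.60, and higher CDKN1A, at 142 ± 6.2 against 104 ± 7.3. LGALS9 was at 4.69 ± 0.064 with empty vector and CDKN1A at 107 ± 0.34. CD38, a surface ectoenzyme of germinal centre and plasma cells, was also higher (log2 fold change 0.48, SE 0.08), while the peroxisomal enzyme PHYH (-1.08, SE 0.13) and DIRAS1 (-1.11, SE 0.12) were lower. KREMEN2, a Dickkopf receptor that restrains Wnt signalling, was higher by 1.46 (SE 0.24), a call that was lost without delta27-BCL7A replicate 2.

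The interferon response genes lay higher in that comparison, with 3 of 31 higher and 0 lower (6 and 0 adjusted over the list alone; median log2 fold change 0.15; camera adjusted p = 0.000902, and adjusted p = 0.709 with an estimated correlation). The p53 targets were higher in 4 of 24 and lower in 0 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00614, and adjusted p = 0.638 with an estimated correlation). TRAC, a T cell receptor transcript that OCI-LY1 also carried with empty vector at 13.6 CPM ± 0.13 (SD, n = 2), was at 17.8 ± 0.99 with the wild type and 12.9 ± 0.17 with the mutant. This call of TRAC was lost without wild-type replicate 1 or either delta27-BCL7A replicate, and with DESeq2. The T cell list held 2 of 6 higher genes and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.0291, and adjusted p = 0.638 with an estimated correlation). Histone transcripts without a poly(A) tail were higher in 1 of 15 and lower in 0 (3 and 0 adjusted over the list alone; median 0.16; camera adjusted p = 0.0359, and adjusted p = 0.709 with an estimated correlation). The limit that the libraries were of polyadenylated RNA applies to these histone transcripts too. In all 521 genes passed the edgeR quasi-likelihood test, 286 higher and 235 lower with the wild type. The count was 113 and 137 without wild-type replicate 1 or 2, and 75 without delta27-BCL7A replicate 2; DESeq2 called 323 and a fit of OCI-LY1 alone 1086. The Spearman correlation of fold change with GC content was 0.483 across genes.

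In VAL, wild-type BCL7A raised complement receptor CR2, an amplifier of B cell receptor signals, from 23.9 CPM ± 3.5 (SD, n = 2) with empty vector to 41.2 ± 0.24, and the B cell kinase PRKCB from 21.2 ± 3.1 to 32.9 ± 1.4. TNF, the inflammatory cytokine, rose from 6.63 CPM ± 0.61 to 11.1 ± 0.77. SERPINA9, a marker of germinal centre B cells, rose from 14.7 ± 0.56 to 26.5 ± 0.43, and DNASE1L3, a secreted nuclease, from 3.82 ± 0.71 to 7.79 ± 1.1. VEGFA fell from 29.7 ± 1.8 to 19.7 ± 0.43, and the adenylate kinase AK5 from 8.63 ± 0.75 to 4.68 ± 0.081.

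The NF-kB targets were higher in 4 of 24 and lower in 0 (14 and 0 adjusted over the list alone; median log2 fold change 0.18; camera adjusted p = 9.14e-11, and adjusted p = 0.165 with an estimated correlation). B cell receptor signalling genes were higher in 4 of 27 and lower in 0 (4 and 1 adjusted over the list alone; camera adjusted p = 1.18e-06, and adjusted p = 0.0709 with an estimated correlation). The cholesterol biosynthesis genes were lower in 2 of 22 and higher in 0 (8 and 0 adjusted over the list alone; median -0.14; camera adjusted p = 1.07e-10, and adjusted p = 0.417 with an estimated correlation). The p53 targets were higher in 2 of 24 and lower in 0 (10 and 1 adjusted over the list alone; camera adjusted p = 0.000295, and adjusted p = 0.224 with an estimated correlation). Mitochondrial transcripts were lower in 2 of 13 and higher in 0 (5 and 0 adjusted over the list alone; median -0.07; camera adjusted p = 3.63e-05, and adjusted p = 0.417 with an estimated correlation). In all 276 genes passed the edgeR quasi-likelihood test, 151 higher and 125 lower. The count was 112 without empty vector replicate 1, 497 without wild-type replicate 2 and 146 in a fit of VAL alone. The Spearman correlation of fold change with GC content was 0.233 across genes.

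Delta27-BCL7A in VAL lowered 15 of 22 cholesterol biosynthesis genes, 16 of 31 interferon response genes, 9 of 24 NF-kB targets and 12 of 20 B cell surface markers relative to empty vector, and raised 12 of 27 S phase genes and 8 of 13 mitochondrial transcripts. Camera called these lists, but none with an estimated correlation (adjusted p = 0.0637 to 0.0646). LSS, an enzyme of sterol synthesis, fell from 121 CPM ± 13 (SD, n = 2) to 88.7 ± 1.7, and MVD from 65.4 ± 5.8 to 48.0 ± 1.0. The interferon-induced genes IFI44L and XAF1 fell from 108 ± 9.9 to 66.1 ± 9.8 and from 47.7 ± 2.3 to 30.1 ± 3.8. The costimulatory receptor CD40 fell from 82.0 ± 1.7 to 63.7 ± 2.1, while RRM2, a subunit of ribonucleotide reductase, rose from 408 ± 31 to 506 ± 9.1. The cholesterol transporter ABCG1 fell by a log2 fold change of 1.27 (SE 0.21).

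Of 22 cholesterol biosynthesis genes, 15 were lower and 0 higher in that comparison (21 and 0 adjusted over the list alone; median log2 fold change -0.34; camera adjusted p = 1.49e-24, and adjusted p = 0.0637 with an estimated correlation). Of 31 interferon response genes, 16 were lower and 0 higher (22 and 0 adjusted over the list alone; median -0.32; camera adjusted p = 1.38e-20, and adjusted p = 0.0646 with an estimated correlation). NF-kB targets were lower in 9 of 24 and higher in 0 (14 and 1 adjusted over the list alone; median -0.25; camera adjusted p = 1.34e-09, and adjusted p = 0.0645 with an estimated correlation). B cell surface markers were lower in 12 of 20 (18 adjusted over the list alone, where 1 was higher; median -0.20; camera adjusted p = 6.54e-14, and adjusted p = 0.0637 with an estimated correlation). MHC class II genes were lower in 8 of 13 (11 adjusted over the list alone; camera adjusted p = 1.7e-11) and MHC class I genes in 9 of 14 (10 adjusted over the list alone; camera adjusted p = 3.47e-10), both with an adjusted p = 0.0637 with an estimated correlation. S phase genes were higher in 12 of 27 (19 adjusted over the list alone; median 0.14; camera adjusted p = 1.37e-14) and mitochondrial transcripts in 8 of 13 (9 adjusted over the list alone, where 1 was lower; median 0.30; camera adjusted p = 4.2e-15), both with an adjusted p = 0.0637 with an estimated correlation. In all 875 genes passed the edgeR quasi-likelihood test, 427 higher and 448 lower. The count was 210 and 517 without empty vector replicate 1 or 2, 145 and 184 without delta27-BCL7A replicate 1 or 2, and 321 in a fit of VAL alone. The Spearman correlation of fold change with GC content was -0.25 across genes.

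Wild-type against delta27-BCL7A in VAL gave higher values with the wild type for 16 of 24 NF-kB targets, 10 of 13 MHC class II genes, 21 of 31 interferon response genes, 8 of 14 MHC class I genes and 14 of 20 B cell surface markers. With an estimated correlation, camera still called the NF-kB and MHC class II lists (adjusted p = 0.0469 for both) but not the interferon list (adjusted p = 0.0949) or the MHC class I and B cell surface lists (adjusted p = 0.0511 for both). TNF was at 11.1 CPM ± 0.77 (SD, n = 2) against 5.21 ± 0.20, the survival gene BCL2A1 at 31.5 ± 4.1 against 17.2 ± 2.1, and CR2 at 41.2 ± 0.24 against 22.5 ± 0.84. MX1, an interferon-induced antiviral GTPase, was at 512 ± 6.0 against 372 ± 36, and HLA-B, an antigen-presenting MHC class I chain, at 1040 ± 79 against 764 ± 15. TERT, the catalytic subunit of telomerase, was lower with the wild type, at 11.9 ± 1.9 against 21.5 ± 0.72, as was the mitochondrial transcript MT-ND2, at 882 ± 6.3 against 1470 ± 30.

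Of 24 NF-kB targets, 16 were higher and 0 lower with the wild type (19 and 0 adjusted over the list alone; median log2 fold change 0.43; camera adjusted p = 9.18e-20, and adjusted p = 0.0469 with an estimated correlation). Of 31 interferon response genes, 21 were higher and 0 lower (25 and 0 adjusted over the list alone; median 0.38; camera adjusted p = 9.18e-20, and adjusted p = 0.0949 with an estimated correlation). MHC class II genes were higher in 10 of 13 (11 adjusted over the list alone; median 0.29; camera adjusted p = 3.96e-13, and adjusted p = 0.0469 with an estimated correlation). MHC class I genes were higher in 8 of 14 (10 adjusted over the list alone; median 0.25; camera adjusted p = 5.22e-12) and B cell surface markers in 14 of 20 (14 adjusted over the list alone; median 0.32; camera adjusted p = 1.33e-13), both with an adjusted p = 0.0511 with an estimated correlation. The share of reads aligned to more than 1 place was 9.86% and 9.70% in the wild-type libraries and 8.32% and 9.01% in the delta27-BCL7A libraries, and the share with low alignment quality was also higher with the wild type. HLA genes share reads with near-identical copies, so the values of single members are uncertain. Lymphoma chromatin regulators were lower in 4 of 20 and higher in 0, and lower in 1 after correction for GC content (5 and 0 adjusted over the list alone; median -0.18; camera adjusted p = 7.43e-06, and adjusted p = 0.181 with an estimated correlation), and S phase genes in 9 of 27 (14 adjusted over the list alone; median -0.13; camera adjusted p = 4.59e-09, and adjusted p = 0.134 with an estimated correlation).

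The mitochondrial transcripts were lower with the wild type than with the mutant in VAL in 10 of 13 cases (10 adjusted over the list alone; median log2 fold change -0.48; camera adjusted p = 1.1e-17, and adjusted p = 0.0511 with an estimated correlation). MT-ND2 and MT-ND3 both had -0.74 (SE 0.06), whereas MT-CO1 (0.07, SE 0.06), MT-CO3 (0.05, SE 0.06) and MT-CYB (0.06, SE 0.05) did not pass the edgeR quasi-likelihood test, at adjusted p = 0.493, 0.621 and 0.49. The mitochondrial genome gave 2.68% to 3.1% of the gene counts in VAL. Among markers of other cell types, TRAC was higher by a log2 fold change of 0.94 (SE 0.21) and COL1A1, a collagen gene of fibroblasts, by 1.57 (SE 0.42), at 1.11 CPM ± 0.13 (SD, n = 2) against 0.369 ± 0.0057. TRAC lost its call without wild-type replicate 1 or delta27-BCL7A replicate 1, and COL1A1 lost it without any of the 4 libraries. In all 1547 genes passed the edgeR quasi-likelihood test, 774 higher and 773 lower with the wild type. The count was 649 and 2417 without wild-type replicate 1 or 2, 438 and 653 without delta27-BCL7A replicate 1 or 2, and 907 in a fit of VAL alone. The Spearman correlation of fold change with GC content was 0.391 across genes.

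**Figure D2:**
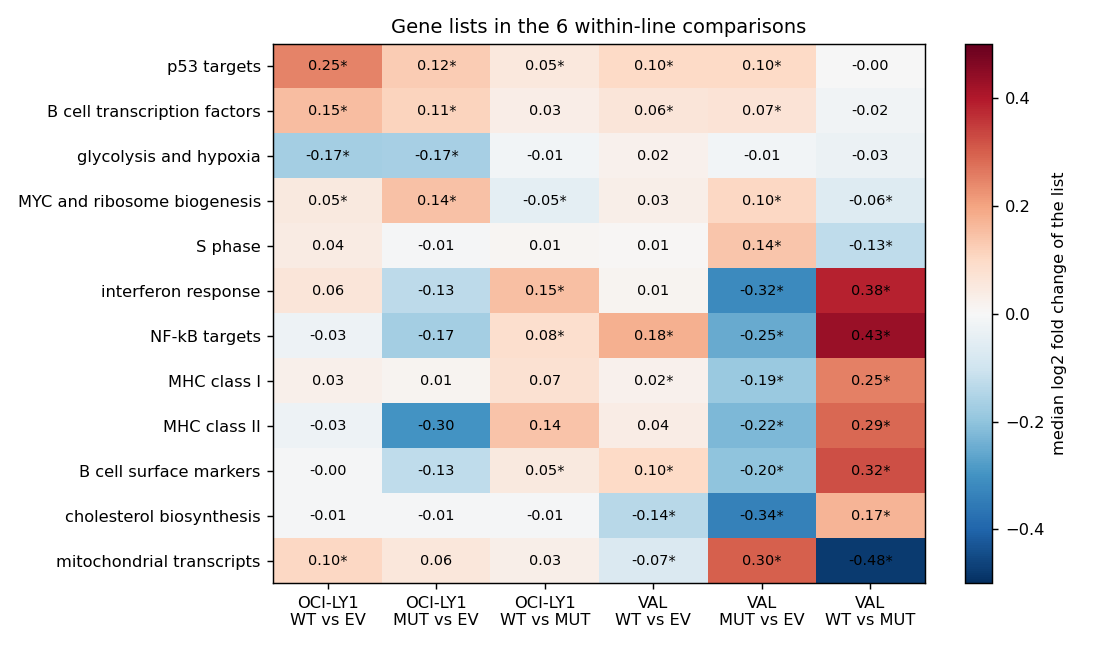
Median log2 fold change (colour and number) of 12 gene lists in the 6 within-line comparisons; an asterisk marks a camera adjusted p below 0.05. The NF-kB, interferon, MHC and B cell surface lists had positive medians of 0.25 to 0.43 in VAL wild-type against delta27-BCL7A. Asterisks refer to the preset correlation. With an estimated correlation, only the NF-kB and MHC class II lists in VAL wild-type against delta27-BCL7A kept a call.

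**Figure D3:**
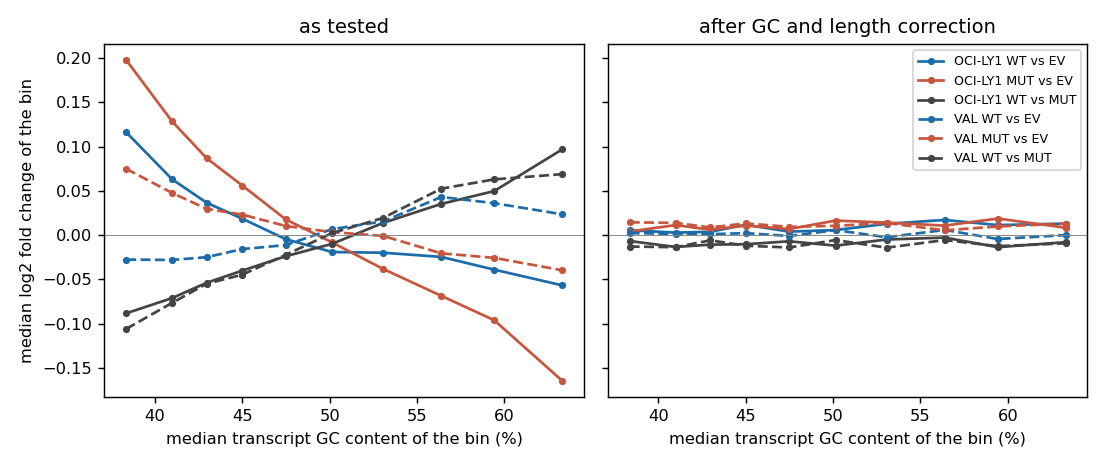
Median log2 fold change (vertical axis) of genes in 10 bins of transcript GC content (horizontal axis) in the 6 within-line comparisons, as tested (left) and after correction for GC content and length (right); solid lines are OCI-LY1 and dashed lines VAL. In OCI-LY1 with delta27-BCL7A the median went from 0.20 in the bin with the lowest GC content to -0.16 in the highest.

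Some genes moved in the same direction in both lines with wild-type BCL7A. VEGFA fell in OCI-LY1 (log2 fold change -1.09, SE 0.09) and in VAL (-0.59, SE 0.09), and so did DEPTOR, an inhibitor of mTOR (-0.79, SE 0.23, and -0.67, SE 0.09). DUSP6, a phosphatase of ERK (0.71, SE 0.15, and 0.93, SE 0.18), and RAG1, the recombinase of antigen receptor genes (0.56, SE 0.09, and 0.72, SE 0.13), rose in both. In the mean over lines, the p53 targets were higher in 14 of 24 and lower in 1 (15 and 1 adjusted over the list alone; median 0.15; camera adjusted p = 6.08e-12, and adjusted p = 0.0448 with an estimated correlation). Within the lines these calls lay mostly in OCI-LY1, with 13 higher, against 2 in VAL (15 and 10 adjusted over the list alone). Camera called the list in both lines (adjusted p = 9.45e-10 in OCI-LY1 and 0.000295 in VAL), though in neither with an estimated correlation. The lines shared 29 genes called higher, against 9.3 for independent lists, and 31 called lower against 6.5 (Fisher's exact test, p = 4.05e-08 and 1.89e-13). In opposite directions, 11 genes were called. Genes are not independent replicates, so these p-values do not measure the spread between libraries. After correction for GC content and length, 104 genes were called in the same direction instead of 60, and 9 in opposite directions. The mean over lines called 1186 genes in the edgeR quasi-likelihood test, 633 higher and 553 lower; it called 519, 577 and 654 without OCI-LY1 empty vector replicate 1, wild-type replicate 1 or wild-type replicate 2, and 1922 without VAL wild-type replicate 1.

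With delta27-BCL7A, the genes that rose in both lines included TMED7 (log2 fold change 1.09, SE 0.10, in OCI-LY1 and 0.36, SE 0.10, in VAL), GMFB, a regulator of actin branching (0.89, SE 0.06, and 0.23, SE 0.06), and the leucine-rich repeat gene LRRC58 (0.77, SE 0.06, and 0.33, SE 0.06). The adhesion molecule CEACAM1 (-1.16, SE 0.19, and -0.40, SE 0.12) fell in both. SULT1A2 fell from 14 to 2 counts in OCI-LY1, a ratio of 6.93 (95% counting interval 1.59 to 62.78), and by a log2 fold change of 0.92 (SE 0.22) in VAL; its reads are shared with near-identical sulfotransferase genes. The lines shared 272 genes called higher, against 44.3 for independent lists, and 227 called lower against 41 (Fisher's exact test, p = 3.24e-163 and 8.97e-118), with 5 in opposite directions. These p-values also treat genes as independent, and fold changes fell with GC content in both lines. After correction for GC content and length, 551 genes were called in the same direction instead of 499, and 8 in opposite directions. The mean over lines called 3861 genes in the edgeR quasi-likelihood test, 2014 higher and 1847 lower, and 2571 without OCI-LY1 delta27-BCL7A replicate 2.

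Between wild-type and delta27-BCL7A, LGALS9, KREMEN2 and F13A1, a transglutaminase subunit, were higher with the wild type in both lines. LGALS9 differed by a log2 fold change of 1.11 (SE 0.14) in OCI-LY1 and 0.70 (SE 0.09) in VAL, F13A1 by 0.66 (SE 0.06) and 1.10 (SE 0.19), and KREMEN2 by 1.46 (SE 0.24) and 1.06 (SE 0.13). The cytoskeletal septin SEPTIN11 (-0.75, SE 0.12, and -0.39, SE 0.06) was lower in both. In OCI-LY1, the call of KREMEN2 was lost without delta27-BCL7A replicate 2. NPTX1, a neuronal pentraxin, was lower in OCI-LY1 (-0.72, SE 0.18) and had 3 counts against 19 in VAL, a ratio of 5.98 (95% counting interval 1.76 to 31.53). In the mean over lines, 20 of 31 interferon response genes were higher and 0 lower (25 and 0 adjusted over the list alone; median 0.24; camera adjusted p = 1.27e-13, and adjusted p = 0.198 with an estimated correlation). Of 24 NF-kB targets, 11 were higher and 0 lower (13 and 0 adjusted over the list alone; median 0.30; camera adjusted p = 2.31e-09, and adjusted p = 0.192 with an estimated correlation). Within the lines these calls lay mostly in VAL, with 21 interferon and 16 NF-kB genes higher, against 3 and 1 in OCI-LY1. The lines shared 116 genes called higher, against 13 for independent lists, and 100 called lower against 10.7 (Fisher's exact test, p = 1.14e-80 and 6.53e-72), with 5 in opposite directions. These p-values also treat genes as independent, and fold changes rose with GC content in both lines. After correction for GC content and length, 149 genes were called in the same direction instead of 216, and 7 in opposite directions. The mean over lines called 2192 genes in the edgeR quasi-likelihood test, 1080 higher and 1112 lower. It called 1256 and 1303 without OCI-LY1 wild-type replicate 1 or 2, 989 without OCI-LY1 delta27-BCL7A replicate 2 and 1113 without VAL delta27-BCL7A replicate 1.

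**Figure D4:**
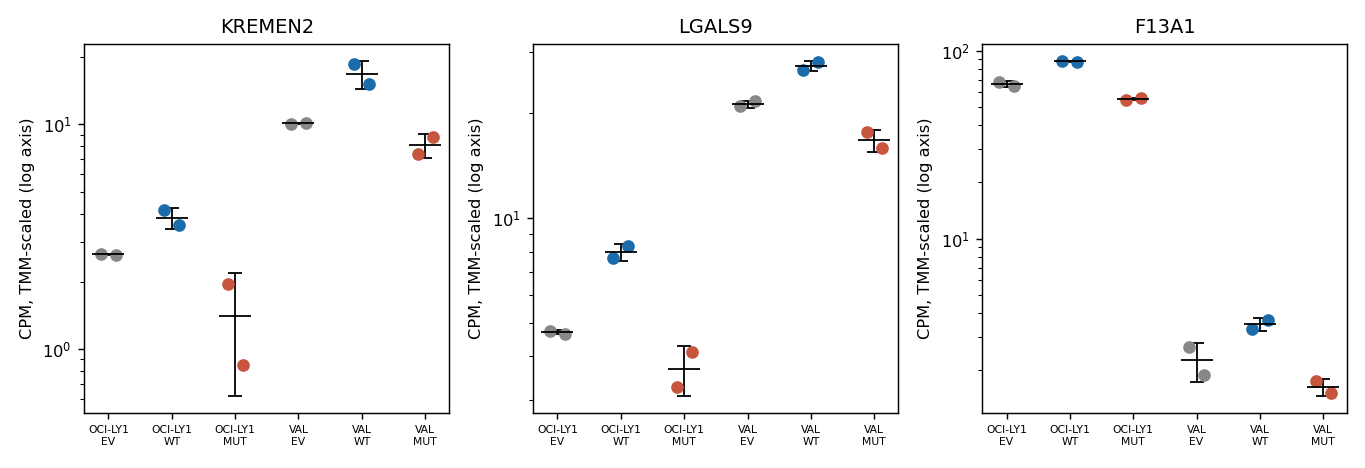
KREMEN2, LGALS9 and F13A1 in CPM (TMM-scaled, log axis) in the 12 libraries by line and construct; points are libraries, dashes the means and bars the SD (n = 2). Means with wild-type BCL7A lay above those with delta27-BCL7A in both lines, as for LGALS9 at 7.98 against 3.68 in OCI-LY1 and 27.3 against 16.7 in VAL.

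Both constructs were set against the same 2 empty vector libraries of a line, which makes their fold changes resemble each other even without an effect. In OCI-LY1, 1319 genes were called in the same direction with both constructs, ZMAT3, MDM2 and VEGFA among them, and 3 in opposite directions. Simulated groups without change that shared the same controls gave 0.2 such genes on average over 20 draws and 2 at most. As these groups held no effect, few calls were likely there in advance. The simulated counts of shared genes, here and for VAL, therefore cannot show how far shared controls raise the overlap of real calls. The Pearson correlation of the fold changes was 0.531 across genes, inside the simulated range of 0.452 to 0.553. In VAL, 37 genes were called in the same direction and 11 in opposite directions, against a simulated maximum of 1. After correction for GC content and length, the counts were 1215 and 7 in OCI-LY1, and 69 and 19 in VAL. The VAL correlation of 0.405 lay below the simulated range of 0.467 to 0.541. With each construct set against its own empty vector library, 558 and 488 genes were called in the same direction in OCI-LY1 for the 2 ways to divide the controls. For genes higher with both constructs these held 383 and 371, against 43.5 and 31.4 for independent lists. The Pearson correlation was then 0.072 and 0.18, and the Spearman correlation 0.267 and 0.374. In VAL the divided controls left 10 and 7 genes in the same direction and 9 and 4 in opposite directions, with correlations of 0.006 and -0.006.

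The response to BCL7A differed between the lines for several of these genes. PTPRF was lower with wild-type BCL7A in OCI-LY1 (log2 fold change -1.57, SE 0.14) and had 0.31 in VAL, a difference of 1.88. FAS rose by 0.95 in OCI-LY1 and had 0.20 in VAL, a difference of -0.75. The edgeR quasi-likelihood test of the difference gave adjusted p = 3.83e-05 and 0.001. It called 663 genes for wild-type BCL7A against empty vector, 258 for delta27-BCL7A against empty vector and 77 for the wild type against delta27-BCL7A. As VAL minus OCI-LY1, 214 of these were higher and 449 lower, 48 higher and 210 lower, and 46 higher and 31 lower, in that order. The first of these counts was 343, 362, 313 and 299 without OCI-LY1 empty vector replicate 1 or 2 or wild-type replicate 1 or 2, 396 without VAL empty vector replicate 1 and 1591 without VAL wild-type replicate 2. The next was 120, 99 and 24 without OCI-LY1 empty vector replicate 1 or 2 or delta27-BCL7A replicate 2, 114 and 578 without VAL empty vector replicate 1 or 2 and 101 without VAL delta27-BCL7A replicate 2. The last was 23, 32, 39 and 29 without OCI-LY1 wild-type replicate 1 or 2 or delta27-BCL7A replicate 1 or 2, 47 and 27 without VAL delta27-BCL7A replicate 1 or 2 and 631 without VAL wild-type replicate 2. BCL7A itself rose less in VAL, by -1.19 and -1.13 on the log2 scale for the constructs, and VAL was collected on another day after transduction, so line, day and level of BCL7A cannot be told apart here.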

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

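The tests of differences between the lines and of chance groupings were chosen before the data were examined, as was leaving out single libraries; the tests with the GC correction and the other tests of explanations below were chosen after results were seen.

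With wild-type BCL7A against empty vector, the response differed between VAL and OCI-LY1 (VAL minus OCI-LY1) for 663 genes in the edgeR quasi-likelihood test, with 299 to 1591 when each library was left out. BCL7A itself rose by a log2 fold change of 1.88 in OCI-LY1 and 0.69 in VAL, a difference of -1.19. The differences of BCL11A (-1.07), FAS (-0.75), VPREB1, a surrogate light chain gene (-0.73), and SPRED1, an inhibitor of RAS signalling (-1.15), came from rises in OCI-LY1. VEGFA (0.49) fell in both lines, and further in OCI-LY1. LRRC32 (1.26) fell in OCI-LY1 and had -0.47 in VAL, and PTPRF (1.88) fell in OCI-LY1 (-1.57) and had 0.31 in VAL. LRRC14B (-1.47), TMEM272 (-1.36) and the receptor TLR4 (-1.23) had opposite signs in the lines, with lower values in VAL. MEST, an imprinted gene, held 8 counts against 0 in VAL, at least 2.72-fold higher against a floor of 3 counts over the group, and LGR4 held 3 counts against 21 in OCI-LY1, a ratio of 6.80 (95% counting interval 2.03 to 35.62). MEST was at 15.9 CPM in OCI-LY1 with empty vector, and its counts in the VAL wild-type libraries were 0.606% and 1.83% of the OCI-LY1 level. For 33 other transcripts of OCI-LY1 absent from VAL with empty vector, the same share was 0.0498% (95% counting interval 0.0215 to 0.0982) and 0.113% (0.0668 to 0.178). Traces of a sex-linked transcript of OCI-LY1, not reported here, also appeared in VAL with wild-type BCL7A, so reads of the other line were not excluded as a source of the MEST counts.

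For delta27-BCL7A against empty vector, 258 genes differed in response between the lines, with 24 to 578 when each library was left out. BCL7A differed by -1.13, TMED7 by -0.73, GMFB by -0.66, LRRC58 by -0.44 and SRP9, a subunit of the signal recognition particle, by -0.82, each with the larger rise in OCI-LY1. MT-ND3 differed by 0.45, with the larger rise in VAL. ZFPM1 (1.54) and ANXA2 (1.27) were lower with the mutant in OCI-LY1, at -1.27 and -1.30, than in VAL, at 0.28 and -0.03. CADPS (-0.99) and LRRC14B (-0.94) went the other way, and ASB13 held 3 counts against 22 in OCI-LY1, a ratio of 7.26 (95% counting interval 2.18 to 37.86).

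For wild-type against delta27-BCL7A, 77 genes differed between the lines, with 23 to 631 when each library was left out. PHYH differed by 1.02 (-1.08 and -0.06) and TERT by -0.84 (-0.01 and -0.85). SDC3, a syndecan (1.74), and ZDHHC14, a palmitoyltransferase (1.86), were lower with the wild type in OCI-LY1 and higher in VAL. AK5 (-1.37) went the other way, at 0.54 in OCI-LY1 and -0.82 in VAL. TP73, a relative of p53 (-1.03), was at 0.84 in OCI-LY1 and -0.19 in VAL. CORO2B differed by 1.69, at -0.29 in OCI-LY1 and 1.39 in VAL.

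Among the gene lists, camera called line differences that no list kept with an estimated correlation, where the lowest adjusted p was 0.0628. For wild-type BCL7A against empty vector the medians of the difference were 0.24 for the NF-kB targets, 0.17 for glycolysis and hypoxia and 0.14 for oxidative phosphorylation. They were -0.21 for the p53 targets, -0.04 for the B cell transcription factors, -0.15 for cholesterol biosynthesis and -0.25 for the mitochondrial transcripts. For delta27-BCL7A against empty vector they were -0.39 for cholesterol biosynthesis, -0.20 for the interferon response, -0.15 for MHC class I, -0.13 for B cell surface markers and -0.081 for germinal centre genes. They were 0.22 for the mitochondrial transcripts, 0.17 for glycolysis and hypoxia, 0.11 for S phase and 0.14 for the unfolded protein and integrated stress response. The p53 targets had a median of -0.10 and a mean of 0.06, of opposite sign. For wild-type against delta27-BCL7A they were 0.29 for the NF-kB targets, 0.21 for cholesterol biosynthesis, 0.18 for the interferon response, 0.15 for B cell surface markers, 0.14 for MHC class I and 0.11 for oxidative phosphorylation. They were -0.48 for the mitochondrial transcripts, -0.13 for S phase, -0.13 for the chromatin regulators, -0.094 for the p53 targets, -0.09 for the stress response genes and -0.073 for G2 and M phase. Line, day of collection and the rise of BCL7A changed together, so the cause was not tested.

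Other divisions of the libraries were counted with an additive fit of line and division on the 8 libraries of a contrast. This is not the fit behind the counts over both lines. In the other splits the construct difference itself widens the spread. Few calls were therefore likely there in advance, and the test cannot exclude chance. Among 34 splits of the same 8 libraries with line as a term, the real grouping included and the split along the lines left out, the real grouping gave 383 genes for wild-type BCL7A against empty vector and the highest other split 148. The real grouping gave 3481 against 1 for delta27-BCL7A against empty vector, and 1813 against 15 for the wild type against the mutant. A batch of virus or of transduction per construct would divide the libraries in the same way, and the cause was not tested.

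Fold changes followed GC content in all 6 within-line comparisons, which a difference in library preparation could produce. After correction for GC content and length, the counts were 2049, 2542 and 444 genes in OCI-LY1 for the wild type against empty vector, the mutant against empty vector and the wild type against the mutant. In VAL they were 360, 1132 and 1374. These counts include genes newly called after the correction. Of the uncorrected calls, 77.7%, 54% and 64.5% were kept in the same direction in OCI-LY1, in that order. In VAL 93.5%, 85% and 63.9% were kept, and in the mean over lines 95.8%, 65.2% and 56.4%. Most calls of each comparison were thus kept. A large part was not for the mutant against empty vector in OCI-LY1, where the lowest share was kept, and over both lines. The same held between the wild type and the mutant. Whether the trend came from the libraries or from the cells was not tested.

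In VAL, the NF-kB, interferon, MHC class I, MHC class II and B cell surface lists were lower with delta27-BCL7A than with the wild type, and the NF-kB and MHC class II calls held with an estimated correlation. Against empty vector the medians were 0.18 with the wild type and -0.25 with the mutant for NF-kB and 0.10 and -0.20 for B cell surface markers, but 0.015 and -0.32 for interferon, 0.02 and -0.19 for MHC class I and 0.04 and -0.22 for MHC class II, where the gap lay mostly on the side of the mutant. No single wild-type or delta27-BCL7A library decided the medians between these constructs. The lowest median without such a library was 69.4% of the full value, for B cell surface markers. After correction for GC content and length the lowest was 77.9%. The medians against empty vector and the calls with an estimated correlation were not recomputed without single libraries. Total BCL7A transcript showed no detectable difference between the constructs, at a log2 fold change of -0.074 (95% interval -0.17 to 0.02). The counts do not separate vector reads from the cell's own, so a difference in dose between the constructs was not excluded. An effect of the wild-type protein, of the mutant protein or of a batch of the transductions of either construct remains possible, and the cause was not tested.

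The mitochondrial transcripts in VAL were lower with the wild type than with the mutant, but unevenly (camera adjusted p = 0.0511 with an estimated correlation). A change in the amount of all mitochondrial RNA does not account for this, as 6 of 13 transcripts lay more than 4 standard errors from their median. Reads counted on nuclear copies were at most 1.27% of the mitochondrial counts. Reads aligned to more than 1 place were counted for neither, so this share cannot show whether they played a part. They made up 9.86% and 9.7% of reads with the wild type and 8.32% and 9.01% with the mutant. After correction for GC content and length, 93.5% of the median remained. MT-ND2 and MT-ND3 differed while MT-CO1 and MT-CO3 did not, so a difference in transcript stability or in how polyadenylated RNA was captured could be involved, and the cause was not tested.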

How the results depend on the processing

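The correction for GC content and length, the fit without mitochondrial genes and the divided empty vector libraries were chosen after results were seen; the other alternatives were chosen before. With a log2 fold change of at least 1 required, the counts in OCI-LY1 were 126 for wild-type BCL7A against empty vector, 219 for delta27-BCL7A against empty vector and 59 for the wild type against the mutant, of which 26, 39 and 53 were higher. They were 18, 14 and 58 in VAL (12, 2 and 41 higher), 31, 101 and 70 over both lines (13, 22 and 64 higher), and 54, 11 and 11 for the line differences (40, 7 and 7 higher). A fit of the line alone called 1086 genes instead of 521 for the OCI-LY1 wild type against the mutant, and 146, 321 and 907 in the comparisons of VAL; DESeq2 called 323 for the OCI-LY1 wild type against the mutant. For the line differences, the mutant against empty vector gave 400 without a filter on low counts and 169 after the GC correction, and the wild type against the mutant gave 144 and 129, and 37 with limma-voom. Leaving out each library gave 744 to 1178, 1265 to 2964 and 75 to 517 genes in OCI-LY1, and 112 to 497, 145 to 517 and 438 to 2417 in VAL, in the same order. It gave 519 to 1922, 2571 to 3671 and 989 to 2853 over both lines, and 299 to 1591, 24 to 578 and 23 to 631 for the line differences. With divided empty vector libraries, genes called in the same direction with both constructs numbered 558 and 488 instead of 1319 in OCI-LY1, and 10 and 7 instead of 37 in VAL. Signs reversed for BCL7A in OCI-LY1 between the wild type and the mutant (-0.01), at 0 with the stricter filter and -0.029 to 0.009 when each library was left out, highest without delta27-BCL7A replicate 2, and after the GC correction in OCI-LY1 with delta27-BCL7A for CHD1 (-0.027), CDK1 (-0.051) and SAMD9 (-0.037), none of which was called there. Of 794 gene results, 740 kept their call with limma-voom, 785 with RLE scaling, 770 with the replicate block and 670 after the GC correction; with DESeq2 it was 661 of 745. Leaving out a library kept 3332 of 4436. Of 146 list calls, 3 held with an estimated correlation, 73 with fry, 131 after the GC correction, and 145 with RLE scaling or the replicate block.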

Other observations

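The lists below were fixed before the data were examined, and they were picked for this part after results were seen. SWI/SNF subunits, the complex to which BCL7A belongs, were higher with delta27-BCL7A than with empty vector over both lines in 8 of 26 cases and lower in 0 (8 and 0 adjusted over the list alone; median log2 fold change 0.05; camera adjusted p = 0.00795, and adjusted p = 0.259 with an estimated correlation). SMARCA4, an ATPase of the complex, rose by 0.18 (SE 0.06) in OCI-LY1 and 0.22 (SE 0.06) in VAL, calls that were each lost without empty vector replicate 1 or either delta27-BCL7A replicate of the line. With wild-type BCL7A, 2 subunits were higher and 1 lower over both lines (2 and 1 adjusted over the list alone), and camera gave an adjusted p = 0.271. The germinal centre genes were not called by camera in any within-line comparison, with adjusted p = 0.198 to 0.933. Camera tests a shift of a list in a shared direction, and single members did change. In VAL wild type against mutant, 4 of 22 were higher and 1 lower (7 and 3 adjusted over the list alone). With wild-type BCL7A against empty vector, 2 were higher and 1 lower in OCI-LY1, and 1 higher and 1 lower in VAL. BCL6, the germinal centre regulator, had log2 fold changes of 0.04 (SE 0.05) and 0.11 (SE 0.05) with wild-type BCL7A in OCI-LY1 and VAL.

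In VAL, adhesion, migration and chemokine receptor genes had a camera call towards higher values with the wild type than with the mutant, while their median was -0.02 and their mean 0.15 (8 of 25 higher and 1 lower, 9 and 2 adjusted over the list alone; camera adjusted p = 0.0112, and adjusted p = 0.181 with an estimated correlation and 0.0631 after correction for GC content and length). Among markers of other cell types, 6 of 14 T cell genes were tested, and the B-cell lines carried LCK at 163 CPM ± 0.62 (SD, n = 2) in OCI-LY1 and 71.8 ± 4.1 in VAL with empty vector. EPCAM, an epithelial gene, was at 24.5 CPM ± 1.9 in OCI-LY1 with empty vector and 17.0 ± 0.53 with wild-type BCL7A, and at 0 in VAL. Cells were sorted for the reporter alone, and whether these transcripts came from the lines themselves was not tested.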
